A study of Homo sapiens with 6 samples.

How the data were processed

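Gene expression was measured in LNCaP cells, an androgen-sensitive human prostate cancer cell line, on Illumina bead arrays, which read biotin-labelled RNA bound to probe-coated beads. Per the labels, cells received a control siRNA (siCTRL, 3 samples) or an siRNA against ATF4 (siATF4, 3 samples), a short RNA that lowers the matching messenger RNA. After 4 days all samples were given 300 nM thapsigargin for 5 h. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER) and so causes ER stress. Labelled RNA was made from 300 ng of total RNA. The submitters' label on siATF4 replicate 3 says that they left it out as an outlier, so the main comparison set 3 siCTRL arrays against siATF4 replicates 1 and 2, and replicate 3 was put back as an alternative. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

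The deposited scanner table held an intensity for each of 47323 probes on each array, per the file headers not normalized, followed by 887 control rows. Its lowest intensities were close to those of the negative controls, so no background had been subtracted. The deposited detection p-value column was found to run in opposite directions in its 2 blocks. In the probe block it held 1 minus the detection p-value and in the control block the p-value itself. The last 770 rows, taken as negative controls, gave back the probe values to within a largest gap of 0.013, and the 99 identifiers present in both blocks had values that added to 1. Probe values were therefore turned before use. A second deposited table held log2 values that the authors had processed. Its columns had the same quantiles and a median of 6.54 on every array, so they had been quantile normalized over all 6 arrays. The submitters' processing notes name limma, with no version or step. Whether the authors corrected the background is not given in the sources used here. No column of per-sample values was left unused.

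Scanner intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with parameters inferred from the detection p-values (neqc), an offset of 16 was added, and log2 values were quantile normalized over the 5 arrays of the comparison. Probes with a detection p under 0.05 on at least 2 of these arrays were kept, which left 20089. Gene names came from the platform annotation, updated through the human RefSeq gene table (assembly GRCh38.p14), used for names only. Of all probes, 30113 had 1 gene symbol, 8 had several and 17202 were not listed in the table of probe names. Through the Entrez identifier 30074 were named, through the accession 18, and 21 kept the annotation's name. Kept probes with 1 symbol covered 11424 genes, and each gene was represented by its kept probe with the highest mean. Among 2974 genes with several kept probes, 467 had a called probe, and 0 had called probes in both directions by limma.

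Differences are siATF4 minus siCTRL on the log2 scale, fitted with limma lmFit and eBayes. Adjusted p-values are Benjamini-Hochberg values over all kept probes, and a probe was called at an adjusted p under 0.05. Standard errors come from the fit, with 3 residual and 4.81 prior degrees of freedom. A probe not above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over the higher of the lowest detected signal and the probe's own signal. The 22 gene lists were written from textbook knowledge before the data were examined, together with the groups, tests, alternatives and naming rule. The 19 lists with at least 5 measured genes were tested with limma camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Named genes were ATF4 and NIBAN1 (FAM129A), which the series title names, the 10 largest falls and 10 largest rises among called genes whose siCTRL and siATF4 values did not overlap, and up to 4 members of each list with the smallest adjusted p. A gene outside this rule is said to have been chosen after its values were seen.

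The fit was tested on simulated data for this comparison, with 20089 probes. Of 89 probes changed by 1 on the log2 scale 55 were called, of 111 changed by 0.5 there were 10, and of 19889 unchanged probes 4. Calls of changed probes with the wrong sign numbered 0 in this limma fit. Small changes were therefore often missed in this simulation. It changed far fewer probes than the 1796 called in the data, which makes the adjusted threshold stricter. Its rates need not hold for the real comparison. Between 18741 and 19844 probes were above background on each array. No pair of arrays shared more than 0.773% of its probe signals exactly, so all arrays were counted as separate samples. The files name no slides, so slide was not fitted as a block. Alternatives were all 6 arrays with and without array weights, no background correction, an offset of 50, median scaling, the authors' log2 table, no and a stricter detection filter, a trended robust variance, the mean of a gene's probes, leaving out each array, and the replicate number as a block. Background parameters from the negative control rows, and an estimated correlation with all 6 arrays, were added after seeing the data. Gene lists for 3 signalling pathways and 7 cell types were also added then, and their results are in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.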

Results

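RNA from 6 LNCaP samples was measured, 3 with control siRNA and 3 with ATF4 siRNA, all under thapsigargin. ATF4 is the transcription factor at the centre of the integrated stress response, the programme that cells start when protein synthesis is slowed by stress. The comparison asks which transcripts differed with ATF4 siRNA during ER stress. No sample went without thapsigargin, so whether a difference needs ER stress cannot be told. Direct effects of the loss of ATF4 cannot be told apart from later ones after 4 days of siRNA. Arrays correlated over kept probes at 0.9951 to 0.9954 within siCTRL, at 0.9943 between siATF4 replicates 1 and 2, and at 0.9882 to 0.9896 between these groups. Replicate 3 of siATF4, which the submitters left out, correlated at 0.9764 to 0.9771 with siCTRL and at 0.9815 to 0.9818 with the other siATF4 arrays. It enters no test below unless named. The number of arrays limits the precision.

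ATF4 messenger RNA fell by 1.74 on the log2 scale (SE 0.0981, 3 against 2 arrays, limma adjusted p = 0.000318), from a mean of 13.47 ± 0.05 (SD, n = 3) to 11.73 ± 0.11 (SD, n = 2). After subtraction of the mean negative control, 33.9% and 31.6% of the brightest probe's siCTRL signal remained in siATF4 replicates 1 and 2, and 34.3% in replicate 3. The remaining share differed between probes. In siATF4 replicates 1, 2 and 3 it was 15.3%, 12.9% and 13.8% for another ATF4 probe. For the dimmest it was 76.1%, 62.6% and 64.2%. All 3 ATF4 probes gave lower signals in every siATF4 array than in every siCTRL array. NIBAN1, the other gene of the series title (also called FAM129A), fell by 1.67 (SE 0.109, adjusted p = 0.000332). Its signal over the negative controls was 24.5% and 22.3% of siCTRL in replicates 1 and 2 and 45.4% in replicate 3.

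**Figure D1:**
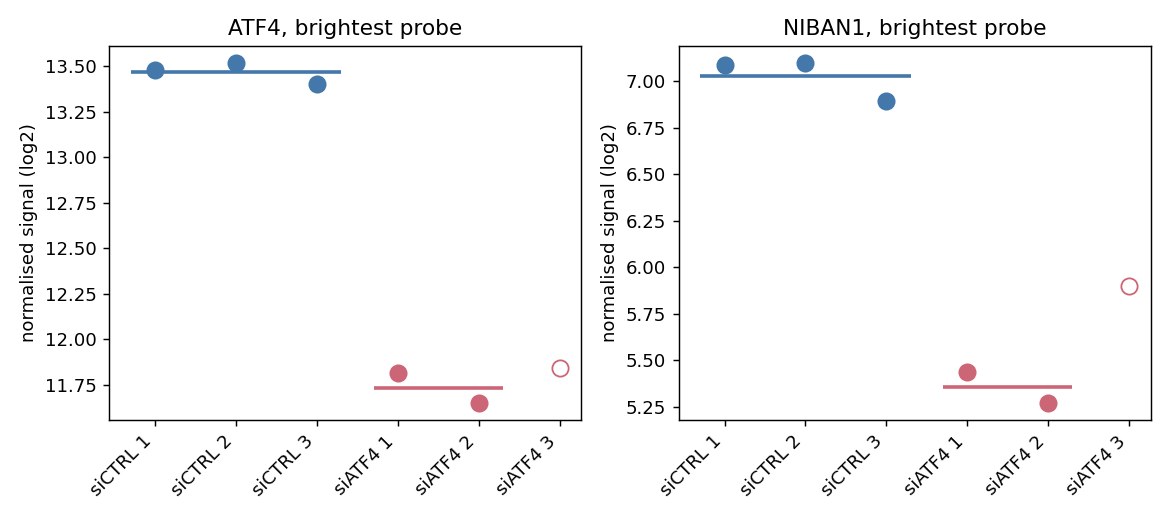
Normalised log2 signal of the brightest ATF4 and NIBAN1 probes on each of the 6 arrays, normalised together. Filled points are arrays of the main comparison, lines are group means, and the open point is siATF4 replicate 3; every siATF4 point lies below every siCTRL point.

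Apart from ATF4, the falls of greatest size included secreted, transport and metabolic genes. STC2, a secreted glycoprotein, fell by 2.81 (SE 0.116, adjusted p = 0.000115). The amino acid transporters SLC7A5 and SLC6A9 fell by 2.26 and 2.09, and GPX8, an ER-resident peroxidase, fell by 1.87, while its second probe stood at -0.51 and was not called. SLC6A9 scanner signals in siATF4 replicates 1 and 2, 112.7 and 100.8, were close to the negative control means of 89.2 and 89.9. The size of the SLC6A9 fall therefore depends on the background correction, as does that of SLC7A5. The calcium-binding protein S100P fell from a mean of 8.72 to 6.72. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 1.85 and ITPRID2 fell by 1.74. CHAC1, which degrades glutathione, fell by 1.74 and was above background on 1 of 2 siATF4 arrays. GCNT3, a mucin-type glycosyltransferase, was not above background in siATF4 and was at least 2.97-fold lower (adjusted p = 0.00242). With all 6 arrays 3 of these calls were lost: STC2 was at -1.81 (adjusted p = 0.167), SLC7A5 at -1.28 (0.327) and GPX8 at -1.39 (0.0513). These losses came with siATF4 replicate 3, where their scanner signals were 942.9, 522.4 and 301.7. In siATF4 replicates 1 and 2 the signals were 186.6 and 177.8 for STC2, 142.1 and 119.3 for SLC7A5, and 156.4 and 150.4 for GPX8. Without any 1 of the 5 arrays the differences were -2.9 to -2.7, -2.6 to -1.9 and -2.0 to -1.8.

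The largest rise in the main fit was that of MMP10, a secreted metalloproteinase, at 2.59 (SE 0.11, adjusted p = 0.000115). Its size depends on the background correction. The MMP10 scanner signals in siCTRL, 101.9 to 106.5, were close to the negative control means of 86.4 to 88.0. They were 261.5 and 301.4 in siATF4 replicates 1 and 2, while PHLDA1 went from 186.3 to 200.9 in siCTRL to 655.1 and 781.7. PHLDA1 rose by 2.26, although its second probe stood at 0.15 and was not called. The phosphatase DUSP5 rose by 1.86, the RNA-binding protein ZFP36 by 1.74, the matricellular protein CCN1 by 1.72 and the TWEAK receptor TNFRSF12A by 1.71. The chemokine CCL8 rose by 1.60, TCIM by 1.56, KLHL41 by 1.51 and HCP5 by 1.49. KLHL41 was also close to the negative controls in siCTRL, with scanner signals of 103.6 to 113.4, so the size of its rise has the same limit. All 10 calls held with all 6 arrays and without any 1 of the 5 arrays.

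Across 11424 genes, 586 were lower and 618 higher with siATF4, and 67 of the lower and 45 of the higher genes differed at least 2-fold. By probe, 864 were lower and 932 higher of 20089, or 8.94%, with 5190 probes at an unadjusted p under 0.05. The median difference of all genes was 0.01. Fewer genes passed with 1 array left out: 313 lower and 269 higher without siCTRL replicate 1, 281 and 256 without siCTRL replicate 2, 355 and 297 without siCTRL replicate 3, 249 and 187 without siATF4 replicate 1, and 232 and 157 without siATF4 replicate 2. With all 6 arrays 421 were lower and 310 higher.

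Regulators and targets of the stress response fell as a list. Of 25 measured members 17 were lower and 2 higher (20 and 3 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 6.3e-12, and adjusted p = 0.11 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, fell by 1.59 (adjusted p = 0.000318), beside STC2, NIBAN1 and CHAC1. The 2 higher members, PPP1R15A at 0.54 and RAB32 at 0.42, were named after their values were seen. PPP1R15A directs the phosphatase that reverses the eIF2 alpha mark. On siATF4 replicate 3 the list's median against siCTRL was -0.89.

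Amino acid genes shifted down as lists. Of 17 measured genes of amino acid and one-carbon synthesis 10 were lower and 0 higher (11 and 0 adjusted over the list alone, 11 lower and 0 higher at an unadjusted limma p under 0.05). The list's median was -0.53 (camera adjusted p = 6.19e-07, and adjusted p = 0.22 with an estimated correlation). The serine synthesis enzymes PSAT1 and PSPH fell by 1.49 and 1.48, the asparagine synthetase ASNS by 1.46, and the mitochondrial folate enzyme MTHFD2 fell by 1.38. Of 14 amino acid transporters 8 were lower and 0 higher (10 and 1 adjusted over the list alone, with 10 lower and 1 higher at an unadjusted limma p under 0.05), and the median was -0.96 (camera adjusted p = 7.57e-08, and adjusted p = 0.18 with an estimated correlation). SLC7A11, the cystine importer, fell by 1.60 and SLC38A1, a glutamine transporter, fell by 1.23. The transporter median was -0.48 without background correction, -0.30 without a detection filter and -0.53 in the authors' deposited log2 values. On siATF4 replicate 3 the medians against siCTRL were -0.82 for synthesis and -0.57 for transport.

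The cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, were lower in 8 of 18 measured members and higher in 0 (11 and 1 adjusted over the list alone, 11 lower and 1 higher at an unadjusted limma p under 0.05). Their median was -0.36 (camera adjusted p = 2.34e-06, and adjusted p = 0.11 with an estimated correlation). GARS1 fell by 1.56, TARS1 by 0.83, YARS1 by 0.77 and EPRS1 by 0.75. Of the 16 mitochondrial synthetases 0 were lower and 0 higher by limma, also over the list alone, and 2 had an unadjusted p under 0.05. Their median was -0.03 while the mean was 0.02 and the test's direction was up (camera adjusted p = 0.972). The difference between these synthetase lists was not tested.

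**Figure D2:**
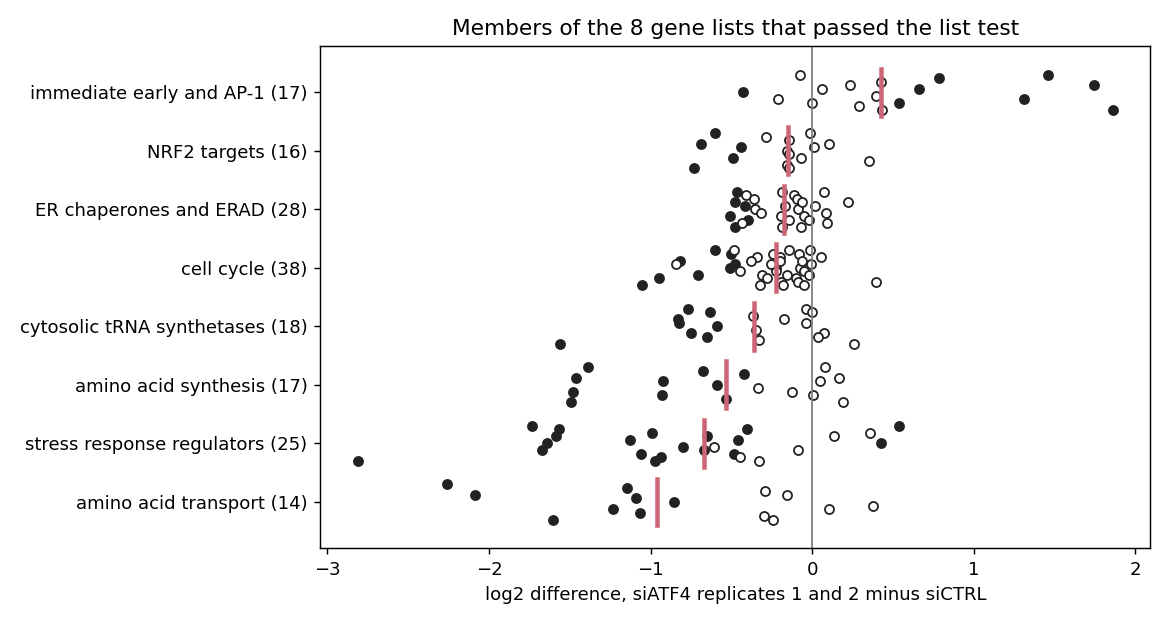
Log2 difference, siATF4 replicates 1 and 2 minus 3 siCTRL arrays, of each measured gene (number in parentheses) in the 8 lists that passed camera with its preset correlation. Filled points are called genes and bars are list medians, from -0.96 for amino acid transport to 0.43 for immediate early genes.

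Genes of ER protein folding and disposal shifted down as a list, with most members not called. Of 28 measured members 6 were lower and 0 higher (11 and 0 adjusted over the list alone, 11 lower and 0 higher at an unadjusted limma p under 0.05), with a median of -0.18 (camera adjusted p = 0.000216, and adjusted p = 0.22 with an estimated correlation). DNAJC10 was at -0.51 (adjusted p = 0.0397), DERL1 at -0.48 (0.0357), SEL1L at -0.48 (0.0315) and DNAJC3 at -0.47 (0.044). The calls of SEL1L, DERL1 and DNAJC3 were lost without each of the 5 arrays in turn, over ranges of -0.58 to -0.36, -0.58 to -0.37 and -0.58 to -0.35. The call of DNAJC10 held only without siCTRL replicate 3 (range -0.62 to -0.41). With all 6 arrays normalised together, the list's median against siCTRL was -0.14, -0.20 and -0.26 on siATF4 replicates 1, 2 and 3.

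Cell cycle genes shifted down as a list in siATF4 replicates 1 and 2, with most members not called. Of 38 measured members 8 were lower and 0 higher (15 and 1 adjusted over the list alone, 17 lower and 1 higher at an unadjusted limma p under 0.05), with a median of -0.23 (camera adjusted p = 4.17e-07, and adjusted p = 0.34 with an estimated correlation). The mitotic kinesins KIF2C and KIF20A fell by 1.05 and 0.82, the centromere histone CENPA by 0.71, and the mitotic kinase AURKA fell by 0.60. With all 6 arrays the list's median was -0.13 and the calls of KIF20A, CENPA and AURKA were lost. The call of CENPA was lost without siATF4 replicate 2, and that of AURKA without siCTRL replicate 2, siATF4 replicate 1 or siATF4 replicate 2 (ranges -0.84 to -0.58 and -0.68 to -0.53). On siATF4 replicate 3 the list's median against siCTRL was 0.05, on the other side of 0. In the same normalization of all 6 arrays it was -0.16 and -0.27 on replicates 1 and 2.

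NRF2 targets, genes of the oxidative stress response, were lower in 5 of 16 measured members and higher in 0 (5 and 1 adjusted over the list alone, 6 lower and 1 higher at an unadjusted limma p under 0.05). The median was -0.15 (camera adjusted p = 0.00263, and adjusted p = 0.24 with an estimated correlation). EPHX1, an epoxide hydrolase, fell by 0.73 and the quinone reductase NQO1 by 0.69. The other called members were GCLC, ME1 and, named after its value was seen, GCLM, whose second probe stood at 0.24 and was not called. The call of NQO1 was lost with all 6 arrays. The call of GCLC held only without siATF4 replicate 1 and that of ME1 only without siCTRL replicate 1 (ranges -0.76 to -0.44 and -0.52 to -0.46).

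Immediate early genes, which respond fast to growth and stress signals, rose as a list. Of 17 measured members 7 were higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2.46e-05, and adjusted p = 0.11 with an estimated correlation). Beside DUSP5 and ZFP36, the AP-1 subunit FOSB rose by 1.46 and the phosphatase DUSP1 by 1.31. FOSB was close to the negative controls in siCTRL, with scanner signals of 95.6 to 102.3, so its size depends on the background correction. The 1 lower member was MYC at -0.43, named after its value was seen, while its second probe, at -0.29, was not called. The median was 0.19 without background correction, 0.26 with an offset of 50 and 0.22 in the authors' deposited log2 values. On siATF4 replicate 3 it was 0.52.

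**Figure D3:**
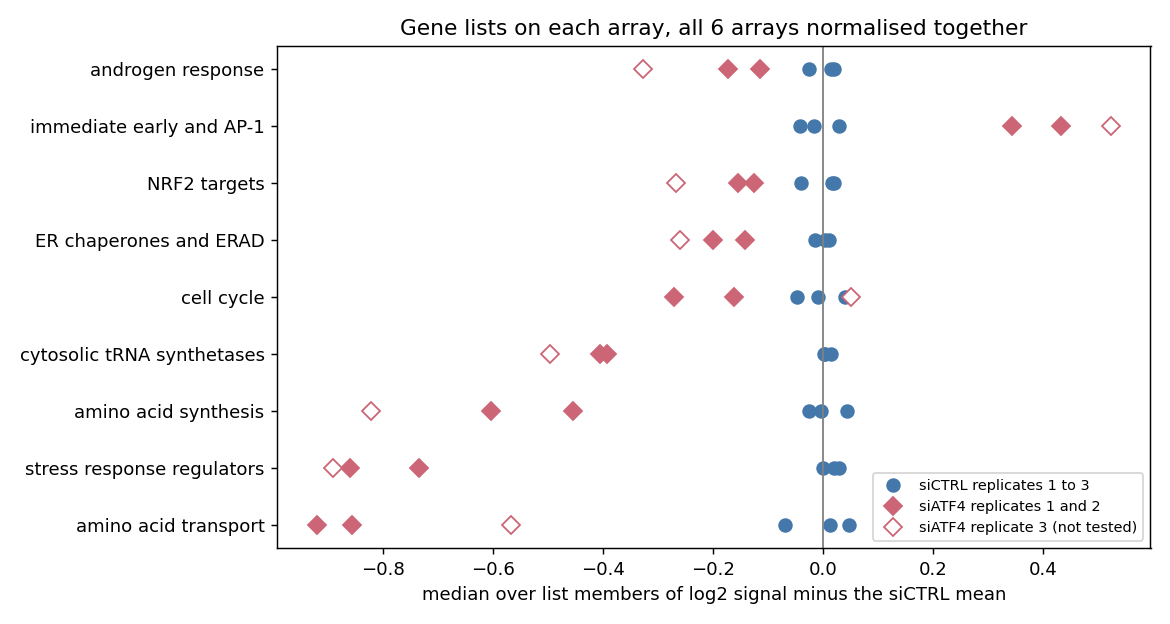
Median over list members of the log2 signal minus the siCTRL mean on each array, with all 6 arrays normalised together, for the 8 lists that passed and the androgen response list. Open diamonds mark siATF4 replicate 3, where the cell cycle median was 0.05 and the androgen response median -0.33.

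The remaining lists did not pass camera. Among 23 androgen response genes 3 were lower and 3 higher (6 and 6 adjusted over the list alone, camera adjusted p = 0.356). Members were tested together whether androgen raises or lowers them, so the list's median does not give the direction of androgen activity. The androgen-inactivating enzymes UGT2B17 and UGT2B15 fell by 0.98 and 0.93. KLK2 stood at 0.54 and ELL2 at 0.60, and both lost their call with all 6 arrays. KLK2 kept it only without siCTRL replicate 2 and ELL2 only without siATF4 replicate 1 (ranges 0.44 to 0.64 and 0.42 to 0.77). With all 6 arrays this list passed, with a median of -0.18 against -0.15 (adjusted p = 0.0424, but 0.656 with an estimated correlation, a test chosen after seeing the data). That pass came with replicate 3, where the median of the members' differences from siATF4 replicates 1 and 2 was -0.41. The list's median against siCTRL was -0.33 on replicate 3, and -0.11 and -0.17 on replicates 1 and 2. Among 23 genes of glycolysis and hypoxia 4 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.222). The vasodilator peptide ADM rose by 0.99 and the glucose transporter SLC2A3 by 0.67, the latter not called with all 6 arrays. Among 24 autophagy and lysosome genes 2 were lower and 1 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.8). The autophagosome protein MAP1LC3B fell by 1.03.

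Among 27 interferon response genes 2 were lower and 3 higher (3 and 4 adjusted over the list alone). The median was 0.06 and the mean 0.01, while the test's direction was down (camera adjusted p = 0.983). OASL stood at 0.71 (adjusted p = 0.00913) and lost its call without siATF4 replicate 1 or siATF4 replicate 2 (range 0.64 to 0.79). Of 19 cholesterol synthesis genes 2 were lower and 0 higher (2 and 0 adjusted over the list alone, 3 lower and 2 higher at an unadjusted limma p under 0.05, camera adjusted p = 0.607). Of 18 p53 targets 2 were lower and 2 higher (3 and 4 adjusted over the list alone, camera adjusted p = 0.8). Of 34 respiratory chain genes 0 were lower and 1 higher (0 and 0 adjusted over the list alone, 0 lower and 3 higher at an unadjusted limma p under 0.05, camera adjusted p = 0.283). Of 40 ribosomal protein genes 1 was lower and 1 higher (1 and 1 adjusted over the list alone, camera adjusted p = 0.389). Of 21 heat shock genes 0 were called by limma, also over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.607).

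Of the named called members of these lists, UGT2B17, UGT2B15, MAP1LC3B, ADM and SLC2A3 kept their call without any 1 of the 5 arrays. The calls of SC5D, INSIG1, CCNG1, DDB2, XPC, SQSTM1, ATG16L1, SLC2A1, NDUFV1, RPL29 and COL1A1 were lost without each of the 5 arrays in turn. The calls of FAS and RPL28 held only without siCTRL replicate 1, that of IRF1 only without siCTRL replicate 3 and that of ISG20 only without siATF4 replicate 1. The call of PFKFB3 was lost without siATF4 replicate 1, and that of OAS3 without siCTRL replicate 2, siCTRL replicate 3 or siATF4 replicate 2. Their values ran from -0.54 for OAS3 to 0.63 for PFKFB3. Counts of called members in all lists depend in part on the probe used. For 12 called members another probe was not called, among them UGT2B15 at -0.60, CENPA at -0.52, ATG16L1 at -0.33, DNAJC10 at -0.31, INSIG1 at -0.06 and PFKFB3 at 0.14. Of members counted as not called, 5 had another probe called lower and 7 another probe called higher. Among them were MSMO1 of cholesterol synthesis, whose 2 other probes were called at -0.50 and -0.40, and the stromal marker VIM, whose other probe was called at 0.72. In the autophagy and lysosome list 3 such members had a probe called higher. Outside the naming rule, and named after their values were seen, PMEPA1 stood at 0.63, KDM3A at 0.52, ISG15 at 0.36 and TRPM8 at -0.43.

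Markers of other cell types were mostly not measured above background. Of 15 stromal markers 6 were measured, with 0 lower and 1 higher (0 and 1 adjusted over the list alone, 0 lower and 3 higher at an unadjusted limma p under 0.05, camera adjusted p = 0.222). Basal, neuroendocrine and leukocyte markers had 3, 3 and 4 measured members and were not tested as lists. Their members did not move together. The neuroendocrine markers ENO2 and TUBB3, not called, were at 0.77 and 0.01. The leukocyte markers HLA-DRA, CD14 and CD79A, also not called, were at -0.27, -0.20 and 0.06. The neuroendocrine marker SYT4 was at -0.75 (adjusted p = 0.00686), a call lost without siATF4 replicate 1 (range -0.85 to -0.64). The leukocyte marker CD68 stood at 0.39 (adjusted p = 0.0471), a call lost without each of the 5 arrays in turn.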

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

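All tests of siATF4 replicate 3 in this part were chosen after its values were seen. This array, which the comparisons do not use, carried signals far above those in the control samples. With all 6 arrays normalised together, 153 of 11749 genes were at least 2-fold above the highest of the other 5 arrays, against 1 gene on siCTRL replicate 2 and 0 on each of the others, and 1 gene was as far below them. These are counts without a test. Over the highest other array, MGP stood 8.71 higher on the log2 scale, MUC1 6.84, KRT19 6.71, CRABP2 6.15 and EFHD1 5.55. The scanner signal of MGP was 13711 on this array and between 93.5 and 106 on the others.

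Of 2 explanations for this excess, normalization did not account for it, and a stronger response to the loss of ATF4 was not decided. A stronger response to the loss of ATF4 would raise these genes in siATF4 replicates 1 and 2 as well. Their median difference from siCTRL there, however, was 0.0381 (quartiles -0.11 and 0.21). These genes were chosen for standing above replicates 1 and 2 too, which works against a rise there, so this median cannot decide. ATF4 itself, by its brightest probe, was at 34.3% of siCTRL, close to the other siATF4 arrays. Normalization was not the source, because all 153 genes were also 2-fold above the other arrays in scanner signals less the mean negative control. RNA or cells of another type in this sample may account for it: 121 genes were above every negative control on this array and not above background on the other 5, against at most 2 on another array.

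Luminal breast epithelium was tried as a candidate source and stays undecided. Of its 20 listed markers 9 had already been seen on this array when the list was written, so the median over all 20, 1.84, is not independent evidence. Over the 11 markers not seen before the median was 0.84 above siATF4 replicates 1 and 2, or 0.65 with markers at background there set to their bound, short of the 1 set as its requirement, and 4 exceeded 1. The same median was 0.11 for androgen receptor negative prostate lines, 0.07 for fibroblasts, 0.03 for melanocytes, -0.03 for liver, -0.04 for colon and -0.04 for leukocytes. The 4 luminal markers over 1 were not above background on siATF4 replicates 1 and 2, so they have only bounds: PIP was at least 181-fold higher here, PGR 7.74-fold, GATA3 6.51-fold and ESR1 4.88-fold. Their scanner signals were 4593, 282.8, 249.1 and 205.7 here and at most 94.2, 92.2, 88.3 and 91.5 elsewhere. The other 7 were under 1. Of the 20 markers 9 were above background in every siCTRL array and 1 was also in another list.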

How the results depend on the processing

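Background parameters from the negative control rows were an alternative chosen after seeing the data, and gave the same counts. So was camera with an estimated correlation on all 6 arrays, where 0 lists passed. ATF4 was called in all alternatives run, between -1.83 and -1.63, no called result reversed, and no called gene was called in the opposite direction. Medians of some lists that did not pass changed sign: with all 6 arrays p53 targets (-0.04) and glycolysis and hypoxia (-0.02), without a detection filter stromal markers (-0.05), and without siATF4 replicate 2 the mitochondrial synthetases (0.03), which also changed sign with median scaling (0.0052). With the mean of probes heat shock genes (0.0016) and p53 targets (-0.0012) changed sign, and p53 targets did without siATF4 replicate 1 (-0.0065). Counts of calls moved more. With all 6 arrays 630 probes and 421 genes were lower, 448 probes and 310 genes were higher, and 712 of the 1204 called genes kept their call. Without background correction 1545 probes were lower and 1701 higher, and 1040 genes lower and 1202 higher. With an offset of 50 these were 1547, 1699, 1029 and 1172, and with a trended robust variance 1608, 1715, 1056 and 1187. With the stricter detection filter 1291 probes and 842 genes were lower, and 1424 probes and 956 genes were higher. Leaving out 1 array gave 341 to 517 probes lower and 233 to 464 higher, and 232 to 355 genes lower and 157 to 297 higher. Where this left 1 siATF4 array, it was assumed to vary like siCTRL. These causes were not tested, apart from the fewer arrays in the last.

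No pairing by replicate number was seen: deviations of same-numbered arrays correlated across probes at -0.06, -0.07 and -0.07, and no sample correlated best with its own number. The siATF4 deviations were taken from a mean that includes replicate 3, so its excess entered all of them. The check therefore cannot exclude pairing. With the replicate block 660 probes and 444 genes were lower, and 582 probes and 380 genes were higher. With the block and all 6 arrays 412 probes were lower and 233 higher, and 272 genes lower and 160 higher. Of the 19 lists 8 passed camera, 9 with all 6 arrays, 0 with an estimated correlation, and 9 and 18 with fry in one and in either direction. The estimated correlation was -0.022 for cytosolic synthetases and -0.0063 for immediate early genes, both below the preset 0.01. For these lists a higher correlation was therefore not why the call was lost. In the other lists that passed it ran from 0.034 for stress response regulators to 0.25 for cell cycle genes. Whether the correlation cost those lists their call was not tested. Of 73 called named genes 43 kept their call without any 1 array and 53 with all 6. The slide block was not run, since the files name no slides. Signal over background limits dim genes: 18741 to 19844 of 47323 probes were above it per array.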

Other observations

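Lists for ERK, SRF and YAP, and NF-kappaB signalling were written after the leading genes had been seen, and the tests of interferon and scaling were chosen after the result was seen. The signalling tests used only members whose values had not been seen, and 1 NF-kappaB member found to have been seen, IRF1, was removed after a first run. Genes in this part were chosen by these lists, outside the naming rule. Of the NF-kappaB list, TNFAIP3, a ubiquitin-editing enzyme, rose by 0.84 (limma adjusted p = 0.0024) and NFKBIA, which holds NF-kappaB in the cytosol, rose by 0.70 (adjusted p = 0.00417), in siATF4 replicates 1 and 2 against 3 siCTRL arrays. SOD2 rose by 0.58. Of 9 unseen NF-kappaB targets 4 were higher and 0 lower. Among 10 unseen SRF and YAP targets 5 were higher and 1 lower. SRF itself rose by 0.93, the actin-binding protein CNN2 by 0.79 and the tropomyosin TPM4 by 0.67, while AJUBA fell by 1.01.

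The rise of immediate early genes was weighed against these lists. An interferon response to transfected RNA would raise most interferon genes, but 4 of 27 were higher at an unadjusted p under 0.05. Scaling between arrays was tested by median scaling alone, where the list kept its direction and call (median 0.41, camera adjusted p = 2.29e-05). Quantile normalization was therefore not the whole cause, although other scalings were not tried. The list also kept both without background correction, with a larger offset and in the authors' log2 values, with a lowest median of 0.19. Those settings were not alternatives to quantile normalization, so they do not test scaling. As hypotheses, NF-kappaB activity (median of unseen members 0.54, camera adjusted p = 8.65e-05) and SRF or YAP activity (0.35, adjusted p = 0.00166) may contribute, though both had an adjusted p = 0.065 with an estimated correlation. ERK output was undecided over 5 unseen members (0.35, adjusted p = 0.289, and 0.54 with an estimated correlation), and off-target effects of the siRNA stay open and untested.

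Replicate 3 of siATF4 moved with the other siATF4 arrays for most called genes. Genes were called from siATF4 replicates 1 and 2 against 2 siCTRL arrays, and replicate 3 was then set against the siCTRL array held out. Of genes called lower 88.3%, 87.7% and 84.2% were lower on replicate 3 with siCTRL replicate 1, 2 or 3 held out, and of genes called higher 88.2%, 92% and 86.2% were higher. Of all genes 53%, 52.8% and 52.9% were lower there.

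In the 10 splits of the 5 arrays into 3 and 2, the real one gave 1796 called probes and the highest other 0 by limma, and only 1 split, the real one, gave as many. In the 10 splits of all 6 arrays the real one gave 1078 and the highest other 0, again with 1 split giving as many. The splits are too few for a share under 0.05. Every other split also mixes siCTRL and siATF4 arrays within a group, so the siRNA difference widens the spread and few calls could arise. The contrast with 0 therefore does not measure chance. Replicate 2 of siCTRL had 5 genes over 1 on the log2 scale above the mean of the other siCTRL arrays, S100A6 (1.76), S100A4 (1.43), CHST2, ALDH1A1 and GPX2, and 0 genes as far below. S100A6 and S100A4 were also raised on siATF4 replicate 3, with scanner signals of 832.2 and 223.9 there against 162 and 150.2 on siCTRL replicate 2. CHST2, ALDH1A1 and GPX2 were not above siCTRL replicate 2 there, at 93.4, 110.1 and 96.7 against 136.9, 122.4 and 122.5. These 3 were above background on 1 of the 2 other siCTRL arrays.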
